A study of Mus musculus with 35 samples.

How the data were processed

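Poly(A) RNA of sorted blood progenitors from mouse thymus, fetal liver, aorta-gonad-mesonephros (AGM) and marrow was amplified with the SMARTer Ultra Low RNA kit and sequenced, per the labels. The cells came from C57BL6 mice with a Rag1-GFP reporter. Reads were aligned with Bowtie to the mm9 build, per the labels, which state no versions, counting tool or annotation.

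The first of the deposited tables gave whole-number read counts per gene for 26 libraries, with RPKM values beside them, in 19613 gene rows. In the second table the authors gave RPKM only, for 9 libraries sequenced separately, in 16747 gene rows. Genes were identified by symbol as listed, and 15437 symbols occurred in both tables. Spreadsheet software had turned 26 symbols of the first table and 23 of the second into dates, and 52 rows of the second joined several symbols. These rows stayed in the tests under the names given, and none was named. The tables were not joined for any test. The 3 T-IP count columns of the first table match their group by name, but also the description of a library of the second table, so they were taken as libraries of that group under the number in the column name. Their 3 RPKM columns were not used.

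Depth varied. Total counts for replicates 1, 2 and 3, in M (1e6 reads), were 2.36, 4.91 and 21.08 for E11.5 thymus T-IP, 3.31, 3.87 and 5.80 for fetal liver LMPP and 6.14, 8.98 and 14.0 for AGM HSPC. Neonatal libraries held 5.37, 11.92 and 21.3 (thymus ETP), 6.01, 11.25 and 11.38 (marrow LMPP) and 5.72, 5.14 and 14.31 (HSC). Adult libraries held 8.08, 8.64 and 4.49 (ETP), 5.44 and 4.16 (LMPP) and 2.07, 3.85 and 2.95 (HSC). Between 12212 and 15572 genes had counts per library, and the ribosomal row Rn45s took 0.039% to 2.613% of them. In the second table the step between low values gave the worth of 1 read, with gene lengths implied by the first table. By this step, 76.0% to 77.6% of low values lay within 0.1 of a whole read, where 20% would by chance, and depth was estimated as 27.3, 28.1 and 23.7 M for T-IP, 24.9, 27.4 and 28.1 M for E12.5 ETP and 38.8, 27.4 and 24.8 M for E13.5 DN2. No pair of libraries in a group of the first table was a copy, since the lowest chi-square per degree of freedom was 10.2. T-IP of both runs correlated at r = 0.829 to 0.907 across 10201 genes, on a scale of counts per kilobase of implied length for the first.

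Groups, comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. Counts were analysed with edgeR 4.0.16 under R 4.3.3. Genes passed filterByExpr with its defaults (14011 genes), libraries were scaled by TMM, and 1 quasi-likelihood model without a block was fitted to all 26 libraries with 17 residual degrees of freedom. The biological coefficient of variation was 0.618. The 11 contrasts of the first table comprised 10 between groups and 1 difference of differences, (T-IP minus fetal liver LMPP) minus (neonatal ETP minus neonatal LMPP). RPKM of the second table were analysed with limma 3.58.1 as log2(RPKM + 1), with eBayes and an intensity trend, over 11276 genes with an RPKM of at least 1 in at least 3 libraries. That model covered all 9 libraries with 6 residual degrees of freedom and gave 2 contrasts. Its log2 changes are on the log2(RPKM + 1) scale, which understates changes of low genes. In both, p-values were adjusted by Benjamini-Hochberg within a comparison, and an adjusted p under 0.05 was the threshold.

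The 20 gene lists were written from general knowledge before the data were examined: Notch targets, T lineage, early lymphoid, B lineage, granulocyte-monocyte, macrophage, dendritic and MHC class II, NK and innate lymphoid, erythroid, megakaryocyte, stem cell, endothelial, thymic and pharyngeal epithelium, mesenchyme, hepatocyte, cell cycle, fetal programme, thymus homing and adhesion, interferon response, and immediate early and heat shock genes. They held 9 to 30 genes and may share members. Each list with at least 3 measured members was tested for direction with fry, adjusted over the lists of a comparison, and camera with a correlation estimated from the data served as the alternative. Members were also adjusted over the list alone.

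Levels of the first table are counts per 1e6 reads of the TMM-scaled library, and those of the second table the deposited RPKM. A group without counts was set to a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% interval from the counts. Genes were named by rule. In each direction the 8 genes with the largest log2 change could be named among those past the threshold, without overlap of replicates and with a group mean of at least 20 CPM or 10 RPKM, leaving out genes of the sorting gates. Up to 4 members past the threshold of a list described could be named, and any member of the Notch, T lineage, early lymphoid, fetal and homing lists whatever its result. Gate genes are given as values.

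Alternatives for the first table were RLE size factors, no filter, a filter of at least 5 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma on the deposited RPKM where no T-IP library entered, replicate number as a block, a fit of only the groups compared, and each library left out in turn. For the second table they were pseudocounts of 0.1 and 5, no filter, a filter of RPKM 5 in 3 libraries, quantile normalization, median centring, the block, only the groups compared, and each library left out. A GC and length offset, and a fit without 4 libraries that stood apart (neonatal HSC 1, neonatal LMPP 3, neonatal ETP 1 and adult ETP 3), were added after the data were seen. The offset came from lowess smooths (span 0.3, 2 passes) of each library against GC content and implied length. GC content was that of the longest GENCODE transcript of a symbol, found for 98.4% of the gene rows.

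The steps were tested on simulated data. For T-IP against fetal liver LMPP, over 13550 genes, edgeR recovered 7.46% of genes changed 2-fold, 43.3% of those changed 4-fold and 80.3% of those changed 8-fold, with 2 false calls, and DESeq2 recovered 19.4%, 67.2% and 90.9% with 31 false calls. For E12.5 ETP against T-IP, over 11276 genes, limma recovered 82.1%, 100% and 100%, with 12 false calls. The labels do not say whether replicates are separate animals or pools, so p-values may measure technical spread in part.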

Results

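Blood progenitors were sorted from mouse embryos at E11.5 (thymus T-IP, fetal liver LMPP and AGM HSPC), from neonates (thymus ETP, marrow LMPP and HSC) and from adults (the same 3 populations). Their RNA was sequenced in a first run of 26 libraries. Each of these 9 groups held 3 replicates, except adult LMPP with 2. A second run of 9 libraries held T-IP again, E12.5 thymus ETP and E13.5 thymus DN2, 3 replicates each. T-IP and E12.5 ETP were CD45+ Lin- c-Kit+ CD25- Flt3+ cells. Later ETP were Lin- CD4- CD8a- c-Kit high CD25- Flt3 high cells, and DN2 were CD45+ Lin- c-Kit+ CD25+ Flt3- cells. LMPP and HSC were sorted as Flt3+ and as Flt3- CD48- CD150+ cells of the Lin- c-Kit+ fraction, and AGM HSPC as Lin- CD45 low VE-cadherin+ c-Kit+ cells. The marrow gates also asked for Sca-1, and the marrow LMPP gates left out CD19 and B220. The E11.5 and neonatal LMPP gates also asked for IL-7Ra, and the adult gate did not. Library totals were 2.07 to 21.3 M (1e6 reads) in the first run. The depth of the second was estimated at 23.7 to 38.8 M reads.

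Gate genes follow as mean ± SD in CPM (counts per 1e6 reads) of the first run. Kit was at 84.4±20.5 in T-IP, 157±51.9 in neonatal ETP and 179.7±42.1 in adult ETP. Flt3 was at 214±40.4 in T-IP, 102±25.4 in fetal liver LMPP, 459±238 in neonatal LMPP and 28.0±11.4 in neonatal HSC. Il7r was at 191±70.8 in T-IP, 175±22.1 in fetal liver LMPP, 241±176 in neonatal LMPP (39.2 in replicate 3) and 5.29±6.99 in adult LMPP. Cdh5, the gene of VE-cadherin, was at 161±13.1 in AGM HSPC and without counts in T-IP. In the second run Il2ra, the gene of CD25, was at 261±22.3 RPKM (reads per kilobase, scaled to library size) in DN2 and 1.52±0.357 in E12.5 ETP.

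Levels are mean ± SD of the group named first against the group named second, with n = 3 in each group unless stated, and log2 changes carry their standard error. A gene was called higher or lower at an adjusted p under 0.05. Members of a gene list were counted as higher, lower or not past it, first over all genes and then, as higher and lower, adjusted over the list alone. Lists were tested with fry, and a camera value, with an estimated correlation, follows where only fry passed. Where a group had 0 counts the fold is a lower bound from a floor of 3 counts over the group. Where it had 1 to 3 counts the ratio comes with a 95% counting interval. Both cover counting error only, not the spread between replicates. With 3 libraries against 3, replicates that do not overlap arise in 10% of random orderings. The 3 T-IP libraries of the first run enter 5 of the 13 comparisons, so those results are not independent.

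**Figure D1:**
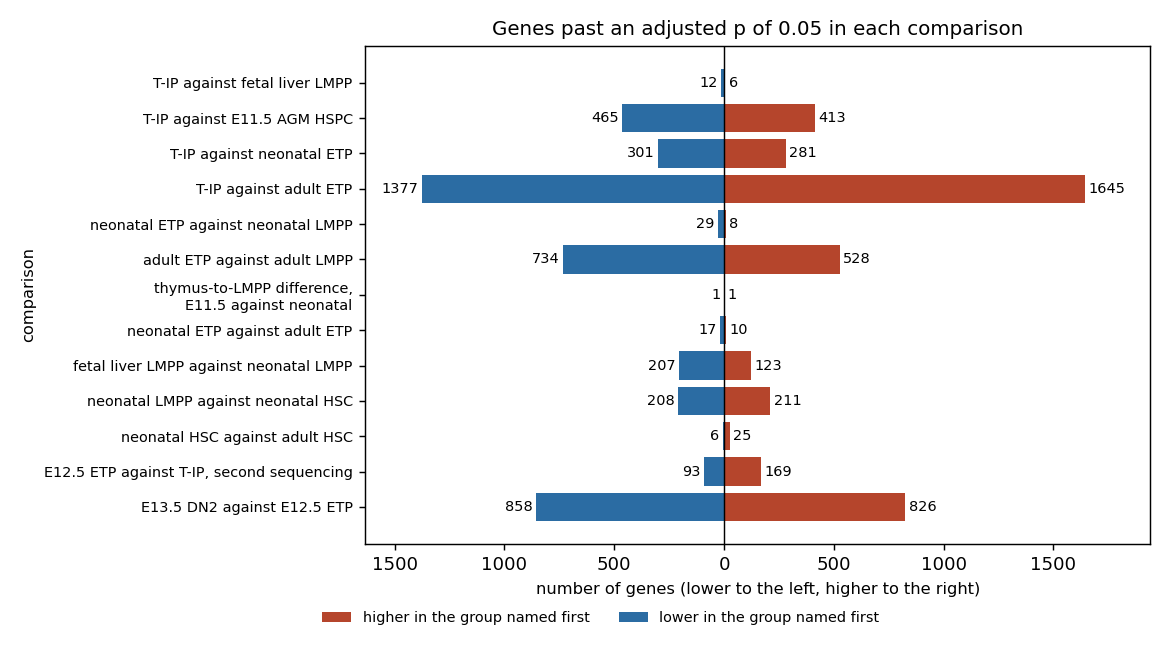
Number of genes past an adjusted p of 0.05 in each of the 13 comparisons, with bars to the right for genes higher and to the left for genes lower in the group named first. The counts run from 2 for the difference of differences to 3022 for T-IP against adult ETP.

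What set the T-IP of the E11.5 thymus apart from the LMPP of the fetal liver on the same day? The T-lineage regulator Gata3 was higher in T-IP (47.6±17.7 against 9.55±2.83 CPM, log2 change 2.30±0.43, adjusted p=0.0298). Lower in T-IP were Cd24a (11.995±6.73 against 86.0±5.29, log2 change -2.80±0.39, adjusted p=0.00105), the heat-stable antigen of immature blood cells, and Tspan6 (21.2±2.99 against 191±52.7, log2 change -3.17±0.39, adjusted p=3.42e-04), a tetraspanin. In all, 18 of 14011 tested genes passed, 6 higher and 12 lower, and 1205 had an unadjusted p under 0.05 (edgeR). The T lineage list lay higher in T-IP (1 higher, 0 lower, 23 not past, 2 and 0 over the list alone, fry adjusted p=0.0162, adjusted p=0.0617 by camera). Cd7, a surface protein of early T-lineage cells, read 200.3±90.8 against 24.7±5.21 (adjusted p=0.171), with Tcf7 at 7.12±2.14 against 1.44±1.05 (adjusted p=0.617).

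The dendritic and MHC class II list also lay higher (0 higher, 0 lower, 13 not past, 2 and 0 over the list alone, fry adjusted p=0.00839). So did thymus homing and adhesion (0 higher, 0 lower, 17 not past, 0 and 0 over the list alone, fry adjusted p=0.0483, adjusted p=0.0968 by camera), where the chemokine receptor Ccr7 read 86.1±28.7 against 18.9±10.1 (adjusted p=0.273). Notch targets did not pass (0 higher, 0 lower, 7 not past, 0 and 0 over the list alone, fry adjusted p=0.384), with Hes1 at 4.28±3.11 against 2.97±0.900 and Nrarp at 0.185±0.321 against 2.83±2.46 CPM. The fetal programme (fry adjusted p=0.171) and early lymphoid list (fry adjusted p=0.894) did not pass either. Of the markers of other cells, hepatocyte genes lay lower in T-IP (0 higher, 0 lower, 5 not past, 0 and 3 over the list alone, fry adjusted p=0.0162, adjusted p=0.0617 by camera). Endothelial genes did so too (0 higher, 1 lower, 23 not past, 0 and 3 over the list alone, fry adjusted p=0.0175, adjusted p=0.0968 by camera). Macrophage (fry adjusted p = 0.886), erythroid (0.707), mesenchyme (0.0882), and thymic and pharyngeal epithelium genes (0.669) did not pass. The balance of directions was not stable. DESeq2 called 112 genes higher and 64 lower, and a fit of these groups alone 142 and 33. That fit raised the adjusted p of the T lineage list to 0.055, the dendritic and MHC class II list to 0.070, the thymus homing and adhesion list to 0.070 and the endothelial list to 0.11. T-IP replicate 3 correlated better in log2 CPM with fetal liver LMPP (mean r 0.923) than with its own group (0.905). The count came to 3, 4 and 36 without T-IP replicates 1, 2 and 3. It was 5, 6 and 4 without fetal liver LMPP replicates 1, 2 and 3. Leaving out 1 library raised the adjusted p of Gata3 to 0.16 and 0.076 (T-IP 1 and 2) and 0.17, 0.15 and 0.060 (fetal liver LMPP 1, 2 and 3) and of the T lineage list to 0.056 (fetal liver LMPP 2). For the thymus homing and adhesion list it rose to 0.073 and 0.090 (T-IP 1 and 2) and 0.056 and 0.25 (fetal liver LMPP 2 and 3), and for the hepatocyte list to 0.051 (fetal liver LMPP 2). It also rose for the endothelial list to 0.073 and 0.090 (T-IP 1 and 2) and 0.051 and 0.098 (fetal liver LMPP 2 and 3).

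How did T-IP differ from the AGM HSPC of the same day, cells of the endothelial wall where the first stem cells arise? T-IP carried a lymphoid and homing set that AGM HSPC all but lacked: Ccr7 (86.1±28.7 against 0 counts, at least 771-fold higher, adjusted p=2.83e-06) and Ccr9 (27.6±2.15 against 1.11±0.399, adjusted p=7.14e-04), receptors that guide progenitors to the thymus, and Cd7 (200.3±90.8 against 0.0369±0.0639, 4190-fold higher, 95% counting interval 751 to 165000, adjusted p=6.87e-06). They also carried Rag2 (67.4±13.6 against 0.926±0.543, log2 change 6.17±0.96, adjusted p=3.32e-04), a subunit of the recombinase of antigen receptor genes. AGM HSPC carried the stem cell regulator Mecom (2.92±2.86 against 197±19.6, log2 change -6.38±1.20, adjusted p=0.00180) and the retinol-binding protein Rbp1 (9.95±3.58 against 435±85.2, log2 change -5.46±0.67, adjusted p=2.17e-05). Vessel genes such as Esam (0.650±0.780 against 170.4±18.1, log2 change -7.55±1.11, adjusted p=2.02e-04) and Tek (1.38±1.85 against 193±32.0, adjusted p=0.00293) were higher there too. Past the threshold were 878 of 14011 genes, 413 higher and 465 lower, while 2901 had an unadjusted p under 0.05.

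By list, T-IP lay higher for thymus homing and adhesion (8 higher, 2 lower, 7 not past, 8 and 2 over the list alone, fry adjusted p=7.65e-06). T lineage genes followed (4 higher, 0 lower, 20 not past, 6 and 0 over the list alone, fry adjusted p=5.93e-05). So did early lymphoid genes (7 higher, 1 lower, 11 not past, 8 and 1 over the list alone, fry adjusted p=0.00121). Examples were Itgb7 (34.4±6.40 against 0.506±0.783, adjusted p=0.00665), an integrin of homing lymphocytes, Tox (156±13.1 against 27.9±9.43, adjusted p=0.00493) and Il2rg (452±117 against 131±38.6, adjusted p=9.46e-04), the shared cytokine receptor chain. Dendritic and MHC class II genes lay higher (5 higher, 0 lower, 8 not past, 10 and 0 over the list alone, fry adjusted p=4.51e-06), with Cd74 (244±149 against 1.69±0.939, adjusted p=6.51e-04). NK and innate lymphoid genes did as well (3 higher, 0 lower, 9 not past, 6 and 1 over the list alone, fry adjusted p=2.20e-04), with Id2 (1258±460.2 against 69.6±32.4, adjusted p=1.46e-04). The granulocyte-monocyte list lay higher (7 higher, 2 lower, 20 not past, 12 and 3 over the list alone, fry adjusted p=0.0169, adjusted p=0.169 by camera), with Tyrobp (587±89.4 against 54.2±1.89, adjusted p=0.00501), but the lysozyme gene Lyz2 (19.8±18.0 against 222±23.3, adjusted p=3.45e-04) was lower.

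Lower in T-IP were endothelial genes (0 higher, 15 lower, 9 not past, 0 and 20 over the list alone, fry adjusted p=1.70e-08), in a comparison where the AGM gate itself selects VE-cadherin. Stem cell genes lay lower (0 higher, 14 lower, 12 not past, 0 and 17 over the list alone, fry adjusted p=5.67e-06), with Mllt3 (3.73±2.17 against 71.1±17.8, adjusted p=6.51e-04). Fetal programme genes lay lower (0 higher, 6 lower, 10 not past, 2 and 8 over the list alone, fry adjusted p=0.00372, adjusted p=0.122 by camera), with the imprinted genes Igf2 (12.55±2.62 against 183±42.8, adjusted p=0.00586) and Plagl1 (0.375±0.474 against 155±28.6, adjusted p=0.00326). Notch targets lay lower (0 higher, 1 lower, 6 not past, 1 and 3 over the list alone, fry adjusted p=0.00145, adjusted p=0.122 by camera), as did megakaryocyte genes (fry adjusted p=9.59e-04, adjusted p=0.0679 by camera). Genes past the threshold numbered 520, 545 and 579 without T-IP replicates 1, 2 and 3. They numbered 571, 522 and 552 without AGM HSPC replicates 1, 2 and 3. With 1 library left out, the adjusted p went up for the granulocyte-monocyte list to 0.13 (T-IP 3) and 0.076 (AGM HSPC 2).

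Which genes separated T-IP from the ETP of the neonatal thymus, both Flt3+ thymus progenitors? Genes of the fetal programme were higher in T-IP: Igf2bp1 (87.1±25.4 against 0.335±0.354, log2 change 8.30±1.09, adjusted p=1.02e-04) and Lin28b (101±30.6 against 12.04±9.06, log2 change 3.08±0.65, adjusted p=0.00681), RNA-binding proteins of fetal cells. So was Arid3a (68.4±12.04 against 5.47±2.17, log2 change 3.63±0.61, adjusted p=0.00108). Neonatal ETP carried more Hes1 (4.28±3.11 against 117±11.1, log2 change -4.70±1.12, adjusted p=0.0163), the best-known Notch target, and Lck (13.3±2.59 against 87.7±27.8, log2 change -2.71±0.58, adjusted p=0.00701), a kinase of T-cell receptor signaling. They also carried more Sell (2.40±1.64 against 258±33.6, log2 change -6.56±0.94, adjusted p=2.50e-04), the homing receptor L-selectin, and Dntt (0.0168±0.0291 against 54.0±25.3, 1520-fold lower, 95% counting interval 273 to 60100, adjusted p=0.00832), the terminal transferase of antigen receptor joining. In all, 582 of 14011 tested genes passed, 281 higher and 301 lower, and 2414 had an unadjusted p under 0.05.

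The fetal programme list lay higher in T-IP (7 higher, 0 lower, 9 not past, 10 and 0 over the list alone, fry adjusted p=9.00e-06), with Igf2 (12.55±2.62 against 0.697±0.713, adjusted p=0.00692) among its members. Notch targets lay lower (0 higher, 3 lower, 4 not past, 0 and 5 over the list alone, fry adjusted p=4.07e-05). So did the T lineage list (1 higher, 4 lower, 19 not past, 2 and 6 over the list alone, fry adjusted p=0.00481, adjusted p=0.131 by camera). The interferon response list lay lower (0 higher, 11 lower, 12 not past, 0 and 18 over the list alone, fry adjusted p=1.58e-06), with Ifi44 (0.448±0.201 against 27.7±2.04, adjusted p=6.33e-04), Isg15 (2.65±1.95 against 30.8±16.8, adjusted p=0.00186) and Usp18 (7.93±2.02 against 67.5±18.9, adjusted p=0.00192). Early lymphoid genes lay lower (1 higher, 6 lower, 12 not past, 1 and 8 over the list alone, fry adjusted p=0.0157, adjusted p=0.164 by camera), but Mef2c (398±82.0 against 145±14.9, adjusted p=0.00190), a lymphoid-priming factor, was higher.

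The granulocyte-monocyte list lay higher in T-IP (8 higher, 1 lower, 20 not past, 12 and 3 over the list alone, fry adjusted p=0.0157, adjusted p=0.164 by camera), with Cybb (179±64.6 against 0.105±0.0722, 1830-fold higher, 95% counting interval 625 to 8860, adjusted p=4.65e-04), an oxidase subunit of phagocytes. Prtn3 (114±135 against 0.787±0.978, adjusted p=0.00330), a granule protease, was higher too. Thymus homing and adhesion genes lay higher (3 higher, 1 lower, 13 not past, 5 and 2 over the list alone, fry adjusted p=0.00747, adjusted p=0.131 by camera), with Ccr7 (86.1±28.7 against 3.61±2.05, adjusted p=0.00108). Id2 (1258±460.2 against 192±59.6, adjusted p=0.00601), a helix-loop-helix factor of innate lymphoid and dendritic cells, was higher. Nkg7 (62.0±25.995 against 655±269, adjusted p=0.00520) was lower. Ly6a, the gene of Sca-1 and a gate gene of marrow cells but not of these, read 1.32±0.417 against 52.3±15.5 (adjusted p=1.36e-07). The number of genes past the threshold was 310, 312 and 371 without T-IP replicates 1, 2 and 3. It was 318 without neonatal ETP replicate 2. Leaving out 1 library raised the adjusted p of Hes1 to 0.083, 0.052 and 0.066 (T-IP 1, 2 and 3) and of Dntt to 0.071 (T-IP 3). For the early lymphoid list it rose to 0.065 (T-IP 3), and for the granulocyte-monocyte list to 0.090 (T-IP 3).

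Did the same kinds of genes separate T-IP from adult ETP? The fetal programme was again higher in T-IP, with Lin28b (101±30.6 against 0.0447±0.0774, 1590-fold higher, 95% counting interval 285 to 62800, adjusted p=1.13e-06) and Igf2bp1 (87.1±25.4 against 0.253±0.0252, log2 change 8.36±1.12, adjusted p=5.37e-05). Hmga2 (733±362 against 107±27.8, log2 change 2.78±0.45, adjusted p=3.20e-04) and H19 (25.4±8.86 against 0 counts, at least 182-fold higher, adjusted p=3.76e-04), an imprinted fetal RNA, were higher as well. Adult ETP carried more Hes1 (4.28±3.11 against 219±72.7, log2 change -5.60±1.17, adjusted p=0.00246) and Nrarp (0.185±0.321 against 16.3±3.05, log2 change -5.78±1.23, adjusted p=0.00287), both Notch targets. They also carried more Dntt (0.0168±0.0291 against 981±143, 25100-fold lower, 95% counting interval 4510 to 993000, adjusted p=2.79e-04) and Sell (2.40±1.64 against 509.7±107, log2 change -7.54±0.98, adjusted p=3.40e-05). Past the threshold were 3022 of 14011 genes, 1645 higher and 1377 lower, while 5103 had an unadjusted p under 0.05.

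The fetal programme list held most of its members higher in T-IP (12 higher, 0 lower, 4 not past, 12 and 0 over the list alone, fry adjusted p=3.73e-07). The interferon response list held most of its members lower (0 higher, 16 lower, 7 not past, 0 and 16 over the list alone, fry adjusted p=2.26e-06), with Ifi44 (0.448±0.201 against 118±30.6, adjusted p=2.05e-05) and Oas3 (5.95±1.60 against 47.1±5.89, adjusted p=3.85e-04). Notch targets lay lower (0 higher, 3 lower, 4 not past, 0 and 3 over the list alone, fry adjusted p=4.39e-04, adjusted p=0.162 by camera). Early lymphoid genes did too (1 higher, 9 lower, 9 not past, 1 and 9 over the list alone, fry adjusted p=4.79e-04, adjusted p=0.141 by camera), with Notch2 (179±58.2 against 728±229, adjusted p=1.87e-04). The T lineage list did not pass (2 higher, 6 lower, 16 not past, 3 and 7 over the list alone, fry adjusted p=0.106), although Cd247 (0.0168±0.0291 against 3.96±2.06, 119-fold lower, 95% counting interval 20.8 to 4760, adjusted p=0.00388), a chain of the T-cell receptor complex, was lower.

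T-IP lay higher for granulocyte-monocyte genes (11 higher, 4 lower, 14 not past, 13 and 4 over the list alone, fry adjusted p=0.00535, adjusted p=0.458 by camera). They lay higher for dendritic and MHC class II (4 higher, 0 lower, 9 not past, 5 and 0 over the list alone, fry adjusted p=4.39e-04, adjusted p=0.194 by camera) and megakaryocyte genes (fry adjusted p=7.54e-05, adjusted p=0.141 by camera). Examples were Fcgr3 (64.3±21.8 against 1.45±1.55, adjusted p=3.20e-04), an Fc receptor of myeloid cells, and Cd74 (244±149 against 2.20±3.23, adjusted p=6.07e-04). Markers of B cells did not pass as a list (fry adjusted p=0.0540), but Cd79b (127±23.9 against 14.6±9.59, adjusted p=2.15e-04) was higher. Homing genes lay higher (6 higher, 2 lower, 9 not past, 7 and 4 over the list alone, fry adjusted p=0.00106, adjusted p=0.264 by camera), with S1pr1 (27.8±3.49 against 0.224±0.387, adjusted p=1.14e-04) and Ccr7 (86.1±28.7 against 5.47±1.83, adjusted p=0.00102). Cd44 (27.8±7.59 against 135±34.9, adjusted p=9.56e-04) was lower. Fitting these groups alone raised the adjusted p of the granulocyte-monocyte list to 0.069 and the dendritic and MHC class II list to 0.058. The granulocyte-monocyte list also rose to 0.13 with a GC and length offset and to 0.052 without 4 libraries that stood apart. The count came to 1999 and 1609 without T-IP replicates 1 and 3. It was 1738 and 1353 without adult ETP replicates 1 and 3. With 1 library left out, the adjusted p went up for the granulocyte-monocyte list to 0.050 (adult ETP 3).

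**Figure D2:**
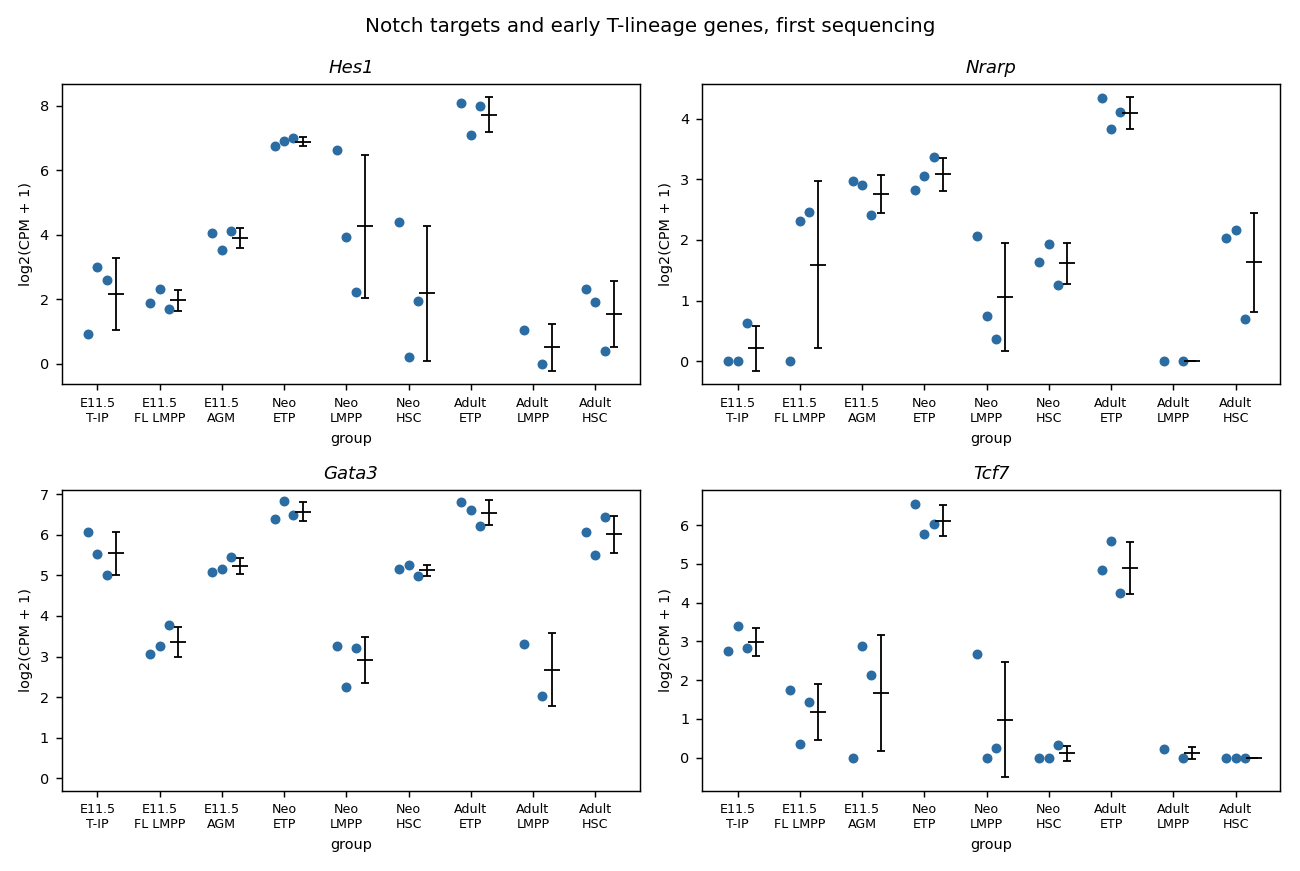
Levels of Hes1, Nrarp, Gata3 and Tcf7 in the 9 groups of the first run, as log2(CPM + 1). Points are libraries, with mean and SD beside them. Hes1 lay at 4.28±3.11 CPM in T-IP against 117±11.1 in neonatal and 219±72.7 in adult ETP. Gata3 lay at 47.6±17.7 CPM in T-IP against 9.55±2.83 in fetal liver LMPP.

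What changed between LMPP of the neonatal marrow and ETP of the neonatal thymus? ETP carried more Gata3 (94.4±15.9 against 6.88±2.71, log2 change 3.78±0.45, adjusted p=1.73e-04) and Cd7 (89.3±38.7 against 5.04±3.13, log2 change 4.14±0.82, adjusted p=0.0315). They carried less Zfp36 (32.7±19.2 against 455±136, log2 change -3.80±0.46, adjusted p=1.73e-04), an RNA-decay factor among the immediate early genes. Rbp1 (3.86±2.49 against 113±101, log2 change -4.92±0.65, adjusted p=5.05e-04) was lower too. In all, 37 of 14011 tested genes passed, 8 higher and 29 lower, and 1270 had an unadjusted p under 0.05. The T lineage list lay higher in ETP (2 higher, 0 lower, 22 not past, 4 and 0 over the list alone, fry adjusted p=1.00e-04). Tcf7, the transcription factor TCF-1, read 70.1±20.7 against 1.87±3.07 (adjusted p=0.106).

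Notch targets lay higher (0 higher, 0 lower, 7 not past, 2 and 0 over the list alone, fry adjusted p=4.05e-04). Hes1 read 117±11.1 against 38.8±51.8 and Nrarp 7.59±1.64 against 1.39±1.57 CPM, neither past the threshold alone (adjusted p=0.675 and adjusted p=0.435). Immediate early and heat shock genes lay lower (0 higher, 3 lower, 17 not past, 0 and 10 over the list alone, fry adjusted p=4.40e-05). So did cell cycle genes (0 higher, 1 lower, 27 not past, 1 and 12 over the list alone, fry adjusted p=0.0108). Early lymphoid (fry adjusted p=0.147) and fetal programme genes (fry adjusted p=0.230) did not pass. Neonatal LMPP replicate 3 stood apart in early lymphoid genes and in Fos (1251, 983 and 134 CPM in replicates 1, 2 and 3, a gene chosen after its values were seen). Without it the early lymphoid list lay lower in ETP (adjusted p = 0.011). A fit of these groups alone called 0 genes. It raised the adjusted p of Gata3 to 0.15, Cd7 to 0.21, Zfp36 to 0.21, Rbp1 to 0.21 and the Notch targets list to 0.13. Without 4 libraries that stood apart the cell cycle list rose to 0.069. Genes past the threshold numbered 6 and 5 without neonatal ETP replicates 2 and 3. Leaving out 1 library raised the adjusted p of Cd7 to 0.11 and 0.10 (neonatal ETP 2 and 3) and 0.086 and 0.13 (neonatal LMPP 1 and 3).

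Did ETP and LMPP differ in the same direction in adults (n = 3 and 2)? Unlike the neonatal one, the adult LMPP gate did not ask for IL-7Ra, so age and gate are mixed. Adult ETP carried more Gata3 (93.4±19.4 against 5.98±4.09, log2 change 3.95±0.54, adjusted p=4.60e-04) and Hes1 (219±72.7 against 0.522±0.738, log2 change 8.54±1.69, adjusted p=0.00565). They carried more Tcf7 (31.0±14.8 against 0.0870±0.123, 344-fold higher, 95% counting interval 61.5 to 13600, adjusted p=0.0214), Nrarp (16.3±3.05 against 0 counts, at least 53.2-fold higher, adjusted p=0.00791) and Ccr9 (94.9±50.2 against 0.824±0.181, log2 change 6.83±1.06, adjusted p=0.00135). Lower in ETP were Rbp1 (0.439±0.439 against 57.2±9.02, log2 change -6.94±0.80, adjusted p=6.65e-05) and Mecom (0.455±0.675 against 74.0±0.0708, log2 change -7.04±1.29, adjusted p=0.00337). So were Prtn3 (0.0893±0.155 against 106±12.46, 1060-fold lower, 95% counting interval 292 to 8750, adjusted p=0.00231) and Cd79b (14.6±9.59 against 106±0.485, log2 change -2.84±0.51, adjusted p=0.00266). Past the threshold were 1262 of 14011 genes, 528 higher and 734 lower, while 3937 had an unadjusted p under 0.05. Notch targets lay higher in ETP (2 higher, 0 lower, 5 not past, 2 and 0 over the list alone, fry adjusted p=9.68e-04, adjusted p=0.148 by camera). The T lineage list did so too (3 higher, 0 lower, 21 not past, 4 and 0 over the list alone, fry adjusted p=0.00103, adjusted p=0.148 by camera).

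Stem cell genes lay lower in ETP (1 higher, 11 lower, 14 not past, 1 and 13 over the list alone, fry adjusted p=0.00131, adjusted p=0.148 by camera). So did granulocyte-monocyte genes (0 higher, 7 lower, 22 not past, 0 and 8 over the list alone, fry adjusted p=0.00162, adjusted p=0.221 by camera), with Csf3r (4.99±2.75 against 62.7±4.56, adjusted p=0.00223). Immediate early and heat shock genes lay lower (3 higher, 7 lower, 10 not past, 3 and 10 over the list alone, fry adjusted p=0.00103, adjusted p=0.148 by camera), with Ier3 (14.1±2.28 against 87.2±9.95, adjusted p=4.60e-04) and Btg2 (54.7±21.4 against 328±39.3, adjusted p=0.00149). With adult LMPP at n = 2, a fit of these groups alone called 43 genes and raised the adjusted p of Gata3 to 0.054, Nrarp to 0.054, Cd79b to 0.11, the T lineage list to 0.072, Csf3r to 0.062, Ier3 to 0.069 and Btg2 to 0.058. A GC and length offset raised that of the immediate early list to 0.25. The number of genes past the threshold was 470, 2510 and 323 without adult ETP replicates 1, 2 and 3. It was 427 and 141 without adult LMPP replicates 1 and 2. With 1 library left out, the adjusted p went up for Hes1 to 0.080 (adult LMPP 2) and for Tcf7 to 0.096 and 0.16 (adult LMPP 1 and 2). For Nrarp it rose to 0.062 and 0.082 (adult LMPP 1 and 2).

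Was the step from LMPP to thymus the same at E11.5 as after birth? The test asked whether the difference between T-IP and fetal liver LMPP differed from that between neonatal ETP and neonatal LMPP. Zfp36 did (log2 difference of differences 4.76±0.62, adjusted p=0.00119). It read 35.5±17.2 CPM in T-IP, 18.4±1.57 in fetal liver LMPP, 32.7±19.2 in neonatal ETP and 455±136 in neonatal LMPP. Angpt1, a ligand of the receptor Tie2, did too (-3.83±0.55, adjusted p=0.00239). It read 33.2±12.6, 185±75.3, 475±193 and 185±60.1 CPM in the same order. In all, 2 of 14011 genes passed, and 824 had an unadjusted p under 0.05.

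Notch targets gained less at E11.5 than after birth (0 higher, 0 lower, 7 not past, 0 and 2 over the list alone, fry adjusted p=0.0152). They had a median difference of differences of -1.49, or -0.997 over the 3 members with more than 3 counts in every group. Immediate early and heat shock genes differed the other way (1 higher, 0 lower, 19 not past, 9 and 0 over the list alone, fry adjusted p=0.00385). They had a median of 2.05, or 2.40 over 14 such members. The T lineage list did not pass (0 higher, 0 lower, 24 not past, 0 and 0 over the list alone, fry adjusted p=0.216). Nor did homing and adhesion (fry adjusted p=0.0764), where Ccr7 differed by 4.48±0.93 (adjusted p=0.101). A GC and length offset raised the adjusted p of Notch targets to 0.090 and of immediate early genes to 0.15. A fit of these groups alone gave 0.093 and 0.051. The count came to 18 without T-IP replicate 3. It was 9 without neonatal ETP replicate 1 and 4 and 6 without neonatal LMPP replicates 1 and 3. Leaving out 1 library raised the adjusted p of the Notch targets list to 0.066 (fetal liver LMPP 3) and 0.055 (neonatal LMPP 3).

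What separated neonatal from adult ETP? Lin28b (12.04±9.06 against 0.0447±0.0774, 165-fold higher, 95% counting interval 29.5 to 6550, adjusted p=0.00193), which blocks maturation of let-7 RNAs in fetal cells, was higher in neonatal ETP, as was Mzb1 (44.1±15.3 against 0.849±1.01, log2 change 5.55±0.75, adjusted p=0.00193). Adult ETP carried more Pgr (0 counts against 61.7±25.6, at least 873-fold lower, adjusted p=0.00301), the progesterone receptor, and more Cpne2 (2.27±1.77 against 33.3±16.0, log2 change -3.92±0.58, adjusted p=0.00277). They also carried more Cdkn1b (83.3±37.1 against 454±195, log2 change -2.45±0.38, adjusted p=0.00301), a cell cycle inhibitor. In all, 27 of 14011 tested genes passed, 10 higher and 17 lower, and 2939 had an unadjusted p under 0.05, and the median of all genes was shifted by 0.11 log2. The fetal programme list lay higher in neonatal ETP (1 higher, 0 lower, 15 not past, 5 and 0 over the list alone, fry adjusted p=0.00670, adjusted p=0.228 by camera), with Igf2bp3 at 170.2±40.4 against 40.8±13.4 CPM (adjusted p=0.0791).

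Notch targets (fry adjusted p=0.383), T lineage (fry adjusted p=0.0990) and early lymphoid genes (fry adjusted p=0.122) did not pass. Hes1 read 117±11.1 against 219±72.7, Tcf7 70.1±20.7 against 31.0±14.8 and Dntt 54.0±25.3 against 981±143 CPM. Part of the spread within these groups went with base composition. The deviation of a library from its group mean correlated across genes with GC content at r = -0.468 and 0.449 for neonatal ETP replicates 1 and 3. It did so at 0.466 and -0.424 for adult ETP replicates 2 and 3, but at 0.0721 and -0.0542 for neonatal ETP 2 and adult ETP 1. Neonatal ETP 1 correlated better in log2 CPM with adult ETP (mean r 0.894) than with its own group (0.870), and adult ETP 2 with neonatal ETP (0.895 against 0.870). A GC and length offset gave 97 genes. A fit of these groups alone called 0 genes, DESeq2 1146 and limma on RPKM 155. Genes past the threshold numbered 597, 9 and 6 without neonatal ETP replicates 1, 2 and 3. They numbered 16, 1771 and 8 without adult ETP replicates 1, 2 and 3. With 1 library left out, the adjusted p went up for Cdkn1b to 0.053 (neonatal ETP 3).

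How did LMPP of the E11.5 fetal liver differ from those of the neonatal marrow? Fetal liver LMPP carried more Igf2bp1 (129±6.29 against 0.586±0.596, log2 change 7.72±1.04, adjusted p=1.51e-04) and H19 (41.7±13.3 against 0.542±0.776, log2 change 6.46±1.13, adjusted p=0.00360). Also higher were Trim71 (29.1±22.1 against 0.171±0.160, log2 change 7.42±1.47, adjusted p=0.00649), a fetal RNA-binding ubiquitin ligase, and Hsph1 (217±42.0 against 29.1±13.9, log2 change 2.90±0.44, adjusted p=6.18e-04), a heat shock protein. Neonatal LMPP carried Dntt (0 counts against 596±372, at least 2220-fold lower, adjusted p=0.00221) and more Zfp36 (18.4±1.57 against 455±136, log2 change -4.63±0.49, adjusted p=1.12e-05) and Ier3 (15.4±4.42 against 93.9±20.2, log2 change -2.61±0.34, adjusted p=9.77e-05). The gate gene Flt3 read 102±25.4 against 459±238, with 188 CPM in neonatal replicate 3. Past the threshold were 330 of 14011 genes, 123 higher and 207 lower, while 2403 had an unadjusted p under 0.05, and the median of all genes was shifted by -0.10 log2.

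The fetal programme list lay higher in fetal liver LMPP (6 higher, 0 lower, 10 not past, 10 and 0 over the list alone, fry adjusted p=7.55e-06), with Igf2 (16.2±6.61 against 0.558±0.894, adjusted p=0.00459). Early lymphoid genes lay lower (0 higher, 4 lower, 15 not past, 0 and 10 over the list alone, fry adjusted p=8.89e-04). So did interferon response genes (0 higher, 5 lower, 18 not past, 0 and 18 over the list alone, fry adjusted p=2.98e-05), with Ddx58 (11.6±2.18 against 76.8±38.9, adjusted p=0.00433), a sensor of viral RNA. Immediate early and heat shock genes lay lower (3 higher, 12 lower, 5 not past, 5 and 12 over the list alone, fry adjusted p=1.85e-04), with Dusp1 (4.56±0.981 against 67.9±39.6, adjusted p=0.00360). Ly6a, selected by the neonatal gate alone, read 2.40±0.336 against 17.0±4.64. The granulocyte-monocyte (fry adjusted p=0.392) and T lineage lists (fry adjusted p=0.344) did not pass. Fitting these groups alone raised the adjusted p of Igf2 to 0.067 and the early lymphoid list to 0.060. A GC and length offset raised that of the immediate early list to 0.065. Neonatal LMPP replicate 3 was low in early lymphoid genes, with Dntt at 886, 725 and 176 CPM in replicates 1, 2 and 3, and in Fos. Without it both lists still lay lower (early lymphoid adjusted p=3.16e-05, immediate early adjusted p=2.48e-05). The number of genes past the threshold was 178, 112 and 108 without fetal liver LMPP replicates 1, 2 and 3. It was 169, 170 and 919 without neonatal LMPP replicates 1, 2 and 3.

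**Figure D3:**
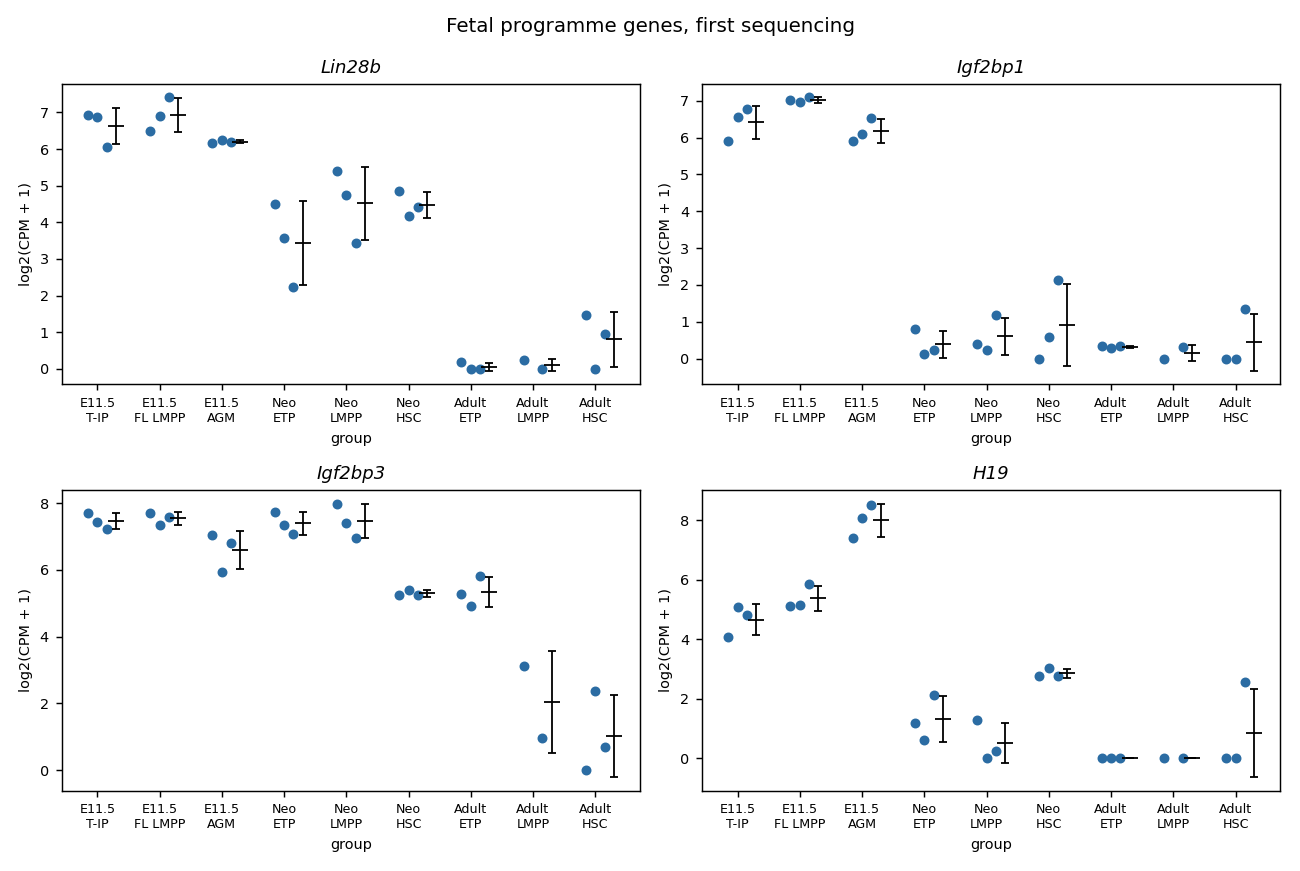
Levels of Lin28b, Igf2bp1, Igf2bp3 and H19 in the 9 groups of the first run, as log2(CPM + 1). Points are libraries, with mean and SD beside them. Igf2bp1 lay at 87.1±25.4, 129±6.29 and 72.4±16.9 CPM in the E11.5 groups and at 0.335±0.354 in neonatal and 0.253±0.0252 in adult ETP.

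What did neonatal LMPP gain over neonatal HSC? Early lymphoid genes were higher: Rag2 (219.7±85.5 against 5.0001±7.70, log2 change 5.51±0.90, adjusted p=0.00147) and Satb1 (104±75.7 against 7.26±4.76, log2 change 3.86±0.69, adjusted p=0.00353), a chromatin organizer of lymphoid cells. The homing receptors Ccr7 (17.8±10.96 against 0.411±0.272, log2 change 5.42±0.80, adjusted p=0.00110) and Ccr9 (35.7±4.83 against 1.71±1.93, log2 change 4.41±0.77, adjusted p=0.00286) were higher too. Cell cycle genes were higher as well, with Top2a (1041±81.9 against 237±63.4, log2 change 2.13±0.31, adjusted p=4.95e-04) and Ccnb1 (729.6±145 against 137±71.6, log2 change 2.41±0.44, adjusted p=0.00369). HSC carried more Mllt3 (17.3±3.77 against 332±133, log2 change -4.26±0.68, adjusted p=0.00116) and Pdzk1ip1 (1.57±2.06 against 102±43.8, log2 change -6.00±1.04, adjusted p=0.00304). Gata3 (6.88±2.71 against 34.1±3.24, log2 change -2.31±0.42, adjusted p=0.00390) was higher in HSC as well. In all, 419 of 14011 tested genes passed, 211 higher and 208 lower, and 2184 had an unadjusted p under 0.05.

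Early lymphoid genes, Flt3 and Il7r of the gates among them, lay higher in LMPP (7 higher, 0 lower, 12 not past, 10 and 1 over the list alone, fry adjusted p=2.30e-05). HSC replicate 1 alone carried Dntt (43.8 CPM against 0 and 0), and LMPP replicate 3 was low in such genes. Without either the list still lay higher (adjusted p=8.42e-06 and 8.43e-08). Cell cycle genes did too (14 higher, 0 lower, 14 not past, 20 and 0 over the list alone, fry adjusted p=1.13e-05). Homing genes lay higher (3 higher, 0 lower, 14 not past, 3 and 1 over the list alone, fry adjusted p=0.00209). So did NK and innate lymphoid genes (2 higher, 0 lower, 10 not past, 5 and 0 over the list alone, fry adjusted p=0.00256). Stem cell genes, Slamf1 of the HSC gate among them, lay lower (0 higher, 12 lower, 14 not past, 0 and 16 over the list alone, fry adjusted p=9.40e-07). Megakaryocyte genes followed (1 higher, 3 lower, 12 not past, 1 and 10 over the list alone, fry adjusted p=1.63e-05). So did erythroid genes (0 higher, 1 lower, 14 not past, 0 and 3 over the list alone, fry adjusted p=4.34e-05) and Esam (2.78±3.52 against 95.04±43.3, adjusted p=0.00556) of the endothelial list. Granulocyte-monocyte genes did not pass as a list (fry adjusted p=0.132), but Cst7 (114±62.9 against 1.19±1.72, adjusted p=0.00431) was higher. Notch targets did not pass (fry adjusted p=0.348). A fit of these groups alone called 20 genes. It raised the adjusted p of Rag2 to 0.098, Satb1 to 0.085, Ccr7 to 0.055, Ccr9 to 0.083, Top2a to 0.055, Ccnb1 to 0.076, Pdzk1ip1 to 0.079, Gata3 to 0.0995, the early lymphoid list to 0.056, Esam to 0.12 and Cst7 to 0.066. The count came to 196 and 109 without neonatal LMPP replicates 1 and 2. It was 272, 177 and 217 without neonatal HSC replicates 1, 2 and 3.

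Which genes separated neonatal from adult HSC? Igf2bp3 (38.5±2.69 against 1.60±2.27, log2 change 4.39±0.68, adjusted p=0.00300) and Lin28b (21.8±5.74 against 0.895±0.883, log2 change 4.78±0.81, adjusted p=0.00733) were higher in neonatal HSC. Hmga2 (253±55.7 against 51.0±26.9, log2 change 2.30±0.45, adjusted p=0.0233), a chromatin protein of fetal stem cells, was too. So were the Y-linked genes Ddx3y (222±195 against 0.993±0.743, adjusted p=0.00123) and Eif2s3y (206±176 against 1.31±1.14, adjusted p=0.00733), which follow the sex of the animals. Past the threshold were 31 of 14011 genes, 25 higher and 6 lower, while 1341 had an unadjusted p under 0.05, and the median of all genes was shifted by 0.11 log2.

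The fetal programme list lay higher in neonatal HSC (3 higher, 0 lower, 13 not past, 3 and 0 over the list alone, fry adjusted p=0.00143). Erythroid genes lay higher (0 higher, 0 lower, 15 not past, 4 and 0 over the list alone, fry adjusted p=0.00266, adjusted p=0.0638 by camera). Stem cell (fry adjusted p=0.986), endothelial (fry adjusted p=0.226), early lymphoid (fry adjusted p=0.239) and Notch target genes (fry adjusted p=0.755) did not pass. Mecom read 275±83.4 against 143±51.7 and Mllt3 332±133 against 204±23.2 CPM. A fit of these groups alone called 14 genes and raised the adjusted p of Igf2bp3 to 0.23, Lin28b to 0.25, Hmga2 to 0.12 and the erythroid list to 0.055. Genes past the threshold numbered 16 and 20 without neonatal HSC replicates 1 and 3. They numbered 17 without adult HSC replicate 2. Leaving out 1 library raised the adjusted p of Hmga2 to 0.089 (neonatal HSC 1) and 0.12 and 0.098 (adult HSC 1 and 3).

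What changed in the thymus between T-IP at E11.5 and ETP at E12.5, both from the second run and in RPKM? The T-lineage regulators Gata3 (37.1±3.23 against 7.62±1.58, log2 change 2.16±0.16, adjusted p=7.49e-05) and Tcf7 (20.002±3.45 against 4.37±2.07, log2 change 2.04±0.26, adjusted p=0.00117) were higher at E12.5. Lck (101±30.8 against 28.9±11.1, log2 change 1.79±0.25, adjusted p=0.00182) and Cd7 (174±34.3 against 73.8±6.87, log2 change 1.21±0.15, adjusted p=0.00101) were as well. The Notch targets Nrarp (2.18±0.184 against 0.135±0.163, log2 change 1.495±0.24, adjusted p=0.00506) and Hes1 (5.21±0.996 against 1.44±0.412, log2 change 1.35±0.25, adjusted p=0.0144) were higher too. Lower at E12.5 were the myeloid genes Mpo (110.1±54.3 against 425±156, log2 change -1.99±0.31, adjusted p=0.00494) and Irf8 (2.44±1.22 against 10.9±0.566, log2 change -1.84±0.25, adjusted p=0.00182). Also lower were Gata2 (1.11±0.233 against 8.30±4.06, log2 change -2.06±0.29, adjusted p=0.00222), a stem and mast cell factor, and Igf2 (1.10±0.155 against 12.8±3.88, log2 change -2.68±0.23, adjusted p=9.06e-05). In all, 262 of 11276 tested genes passed, 169 higher and 93 lower, and 1463 had an unadjusted p under 0.05 (limma).

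Notch targets lay higher (2 higher, 0 lower, 2 not past, 3 and 0 over the list alone, fry adjusted p=0.00266). So did the T lineage list (4 higher, 0 lower, 20 not past, 7 and 1 over the list alone, fry adjusted p=0.0109, adjusted p=0.0888 by camera). Dendritic and MHC class II genes lay higher (4 higher, 0 lower, 9 not past, 8 and 0 over the list alone, fry adjusted p=0.00304), with Cd74 (414±47.9 against 151±28.1, adjusted p=0.00155). NK and innate lymphoid genes lay higher (4 higher, 0 lower, 6 not past, 4 and 2 over the list alone, fry adjusted p=0.00339, adjusted p=0.0780 by camera), with Nkg7 (182±4.28 against 51.1±12.04, adjusted p=9.06e-05) and Gzma (85.8±65.9 against 3.55±0.917, adjusted p=0.00314), a granzyme of killer cells. Interferon response genes lay higher as a list, without a member past the threshold over all genes (0 higher, 0 lower, 15 not past, 12 and 0 over the list alone, fry adjusted p=0.00339). Granulocyte-monocyte genes lay lower (1 higher, 3 lower, 22 not past, 1 and 10 over the list alone, fry adjusted p=0.00304), although Gfi1 (3.30±0.587 against 0.191±0.128, adjusted p=0.00245), a repressor active in granulocytes and T cells, was higher.

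Fetal genes lay lower as a list (0 higher, 4 lower, 8 not past, 0 and 4 over the list alone, fry adjusted p=0.00304), with Lin28a (listed at 0 against 2.49±0.734, adjusted p=0.00185) and Trim71 (listed at 0 against 1.71±0.272, adjusted p=0.00348). Homing and adhesion genes did not pass as a list (3 higher, 1 lower, 13 not past, 4 and 4 over the list alone, fry adjusted p=0.198), but Cxcr4 (11.4±1.41 against 2.62±0.380, adjusted p=3.51e-04), a chemokine receptor, was higher. Early lymphoid genes did not pass (fry adjusted p=0.369), with Cd27 (154±30.7 against 44.9±0.320, adjusted p=9.06e-05), a receptor of lymphocytes, higher. The number of genes past the threshold was 165 without T-IP replicate 2. It was 143 without E12.5 ETP replicate 3. With 1 library left out, the adjusted p went up for Hes1 to 0.059 (T-IP 3) and 0.072 (E12.5 ETP 3).

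What followed from E12.5 ETP to E13.5 DN2? T-cell receptor complex genes were higher in DN2: Cd3e (95.6±27.6 against 1.13±1.53, log2 change 5.69±0.40, adjusted p=9.67e-07) and Cd3g (772±132 against 16.4±21.04, log2 change 6.19±0.60, adjusted p=1.36e-05). So was Lat (71.3±9.9996 against 5.21±3.93, log2 change 3.72±0.41, adjusted p=3.84e-05), an adaptor of the receptor. Bcl11b (3.57±0.563 against listed at 0, adjusted p=1.62e-05), the regulator of T-lineage commitment, and Tcf7 (144±9.54 against 20.002±3.45, log2 change 2.79±0.26, adjusted p=1.05e-05) were higher as well. Lower in DN2 were Cd74 (2.08±0.767 against 414±47.9, log2 change -7.10±0.19, adjusted p=3.02e-10) and Mef2c (0.952±0.0836 against 68.9±4.75, log2 change -5.16±0.14, adjusted p=3.02e-10). So were Csf1r (0.111±0.193 against 12.1±2.97, log2 change -3.55±0.23, adjusted p=3.96e-07) and the thymus-homing receptor Ccr9 (0.198±0.203 against 22.7±6.40, log2 change -4.28±0.26, adjusted p=2.70e-07). Past the threshold were 1684 of 11276 genes, 826 higher and 858 lower, while 3004 had an unadjusted p under 0.05.

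The 4 Notch targets tested passed higher (4 higher, 0 lower, 0 not past, 4 and 0 over the list alone, fry adjusted p=2.52e-05). Among them were Dtx1 (13.8±2.77 against 1.30±0.715, adjusted p=1.87e-05), Hes1 (20.8±7.13 against 5.21±0.996, adjusted p=3.54e-04) and Nrarp (10.2±2.88 against 2.18±0.184, adjusted p=1.99e-04). The T lineage list lay higher (17 higher, 2 lower, 5 not past, 18 and 4 over the list alone, fry adjusted p=1.83e-05), with Lef1 (20.7±5.19 against 0.479±0.220, adjusted p=3.91e-07), but Rorc (0.0267±0.0462 against 6.53±1.63, adjusted p=9.49e-06) and Cd7 (77.5±10.3 against 174±34.3, adjusted p=1.70e-04) were lower. That list also holds the gate gene Il2ra. Dendritic and MHC class II genes lay lower (0 higher, 10 lower, 3 not past, 0 and 11 over the list alone, fry adjusted p=1.83e-05), with H2-Aa (0.376±0.420 against 14.9±2.74, adjusted p=1.27e-06). Granulocyte-monocyte genes did too (2 higher, 10 lower, 14 not past, 2 and 13 over the list alone, fry adjusted p=8.91e-05), with Cybb (listed at 0 against 12.7±5.13, adjusted p=1.91e-06). Endothelial genes followed (0 higher, 6 lower, 3 not past, 0 and 6 over the list alone, fry adjusted p=2.20e-05), with Cd34 (75.7±1.10 against 369±31.1, adjusted p=1.06e-08).

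Homing and adhesion genes lay lower (3 higher, 7 lower, 7 not past, 3 and 9 over the list alone, fry adjusted p=2.48e-05), with Ccr7 (1.002±0.361 against 14.2±4.15, adjusted p=2.94e-06), but Sell (171±66.3 against 5.21±2.83, adjusted p=3.07e-05) was higher. Early lymphoid genes split (5 higher, 4 lower, 9 not past, 5 and 5 over the list alone, fry adjusted p=5.04e-04, adjusted p=0.868 by camera). That list holds the gate gene Flt3. Fry read lower although the median was 0.14, with Rag2 (115±32.5 against 18.3±4.86, adjusted p=4.97e-06) higher and Bcl11a (23.0±4.77 against 59.0±10.8, adjusted p=2.82e-04) lower. NK and innate lymphoid genes lay higher (5 higher, 2 lower, 3 not past, 5 and 3 over the list alone, fry adjusted p=9.80e-05, adjusted p=0.120 by camera), with Nkg7 (798±72.5 against 182±4.28, adjusted p=9.35e-07), while Klrd1 (0.498±0.863 against 27.9±8.04, adjusted p=1.62e-06) was lower. Fetal programme genes read higher by the test with a median of -0.06 (3 higher, 1 lower, 8 not past, 3 and 1 over the list alone, fry adjusted p=0.00110, adjusted p=0.332 by camera), and H19 (257±33.9 against 11.1±3.61, adjusted p=1.80e-07) and Igf2 (26.3±4.32 against 1.10±0.155, adjusted p=3.95e-07) were higher.

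**Figure D4:**
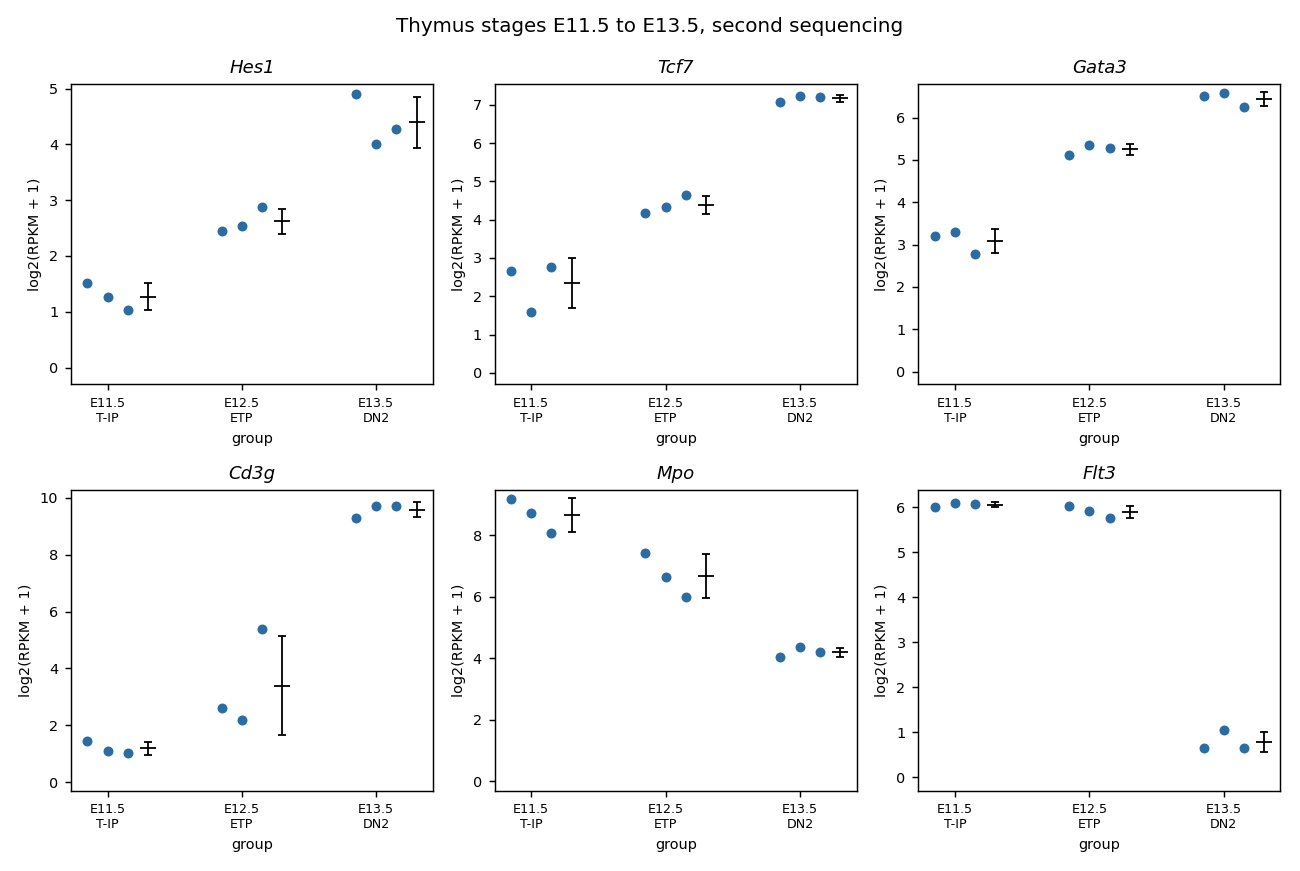
Levels of Hes1, Tcf7, Gata3, Cd3g, Mpo and Flt3 in T-IP, E12.5 ETP and DN2 of the second run, as log2(RPKM + 1). Points are libraries, with mean and SD beside them. Tcf7 lay at 4.37±2.07, 20.002±3.45 and 144±9.54 RPKM and Flt3, a gate gene, at 65.7±2.29, 58.8±5.45 and 0.730±0.281.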

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

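The splits of samples and the base-composition test of neonatal LMPP replicate 3 were set before their results were seen. The tests of stem cell admixture, a fetal liver label, DN2 carry-over, depth and sex were chosen only after the result was seen.

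The difference between thymus and LMPP was not the same at E11.5 and after birth for 2 genes in edgeR's test of the difference itself. These were Zfp36, with a log2 difference of differences of 4.76, and Angpt1, with -3.83. The Notch targets list, with a median of -1.49, and the immediate early and heat shock list, with a median of 2.05, differed as well. Neonatal LMPP held the highest Zfp36 level of the 4 groups, 455±136 CPM. Of 100 splits of the same 12 libraries, 17 gave a count at least as large as the real one of 2, and the highest other split gave 189. Some splits carry the difference between E11.5 and neonatal libraries into the contrast, so this share cannot decide whether chance gave the count. Chance is not excluded.

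Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. For T-IP against fetal liver LMPP (18 genes) and fetal liver LMPP against neonatal LMPP (330) 1 of 10 splits reached the real count, and the highest other split gave 0. For T-IP against AGM HSPC (878), T-IP against neonatal ETP (582), neonatal ETP against neonatal LMPP (37), E12.5 ETP against T-IP (262) and DN2 against E12.5 ETP (1684) it gave 1, and for T-IP against adult ETP (3022) and neonatal against adult HSC (31) it gave 2. These counts are of edgeR for the first table and of limma for the second. For neonatal against adult ETP (27) 2 of 10 splits reached the real count, the other with 1580 genes for neonatal ETP 1 with adult ETP 1 and 3 against the rest. For neonatal LMPP against HSC (419) 2 of 10 did as well, the other with 638 for LMPP 1, LMPP 2 and HSC 1 against the rest. Both point to a structure of the samples apart from age or cell type. In both, the libraries named correlated below 0 with GC content, as deviations from their group means, and the rest above 0. For ETP, r was -0.468, -0.0542 and -0.424 against 0.0721, 0.449 and 0.466. For LMPP and HSC it was -0.255, -0.00783 and -0.369 against 0.223, 0.225 and 0.345. These splits thus followed base composition, and what set that was not tested. Splits were run for groups of 3 libraries, so not for adult ETP against adult LMPP.

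Neonatal LMPP replicate 3 lay below replicates 1 and 2 in 13 of 19 early lymphoid genes, by a median log2 difference of -1.10. Base composition and gene length account for a part at most, since an offset for both moved the median to -0.617. Its quartiles moved from -2.03 and 0.26 to -1.82 and -0.10, so the upper one lay below 0 only with the offset. Admixture of stem cells would need more HSC RNA than the HSC genes show: those 162 genes implied a share of 16.1% (quartiles 3.99 and 40.6), while the loss of early lymphoid genes implied 88.7% (73.7 and 92.7). An E11.5 fetal liver LMPP library under the wrong label is argued against by 55 genes that mark such cells, which implied 30.9% (upper quartile 58.9), below the lowest lower quartile of 62% found for the real fetal liver libraries. Igf2bp1 was at 1.27 CPM in it against 123 to 136 CPM in those. Other values point the other way: its log2 CPM correlated better with fetal liver LMPP (mean r 0.891) than with its own group (0.853), and its Xist, 40.7 CPM, lay in the E11.5 range. What it shares with those libraries stays open. A difference in the IL-7Ra gate or in the cells themselves was not tested and stays open.

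In E12.5 ETP replicate 3, the CD3 genes lay above replicates 1 and 2. Carry-over of DN2 cells or reads is argued against by some abundant DN2 genes. Cd3g, Cd3d and Cd3e implied DN2 shares of 4.75%, 11.7% and 2.75%, but Il2ra implied 0.203%, and 6 of 16 such genes (Anxa2, Gal, Gzmb, H19, Il2ra and Sell) lay under 50% of the lowest of these, although carried-over cells would bring them all. The other 10 lay above that bound, and the median share over 42 genes that mark DN2 was 2.36% (quartiles 0.789 and 4.45). Deeper sequencing is argued against by a depth of 1.03 times that of the next library. T-lineage cells without CD25 inside the ETP gate may account for the pattern, a hypothesis not tested.

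The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to at most 7.20 CPM in the adult libraries, against 136 to 522 CPM at E11.5 and 3.74 to 1054 CPM in neonates. Depth is argued against as a cause, since the E11.5 level would have given at least 532 reads of these genes in each adult library. All 8 adult libraries also had Xist at 231 to 1407 CPM, above the 21.3 to 155 CPM at E11.5, which is consistent with female adults and with pools of both sexes at E11.5. Neonatal ETP lay nearer the adults (Y-linked sum 3.74 to 96.2, Xist 226 to 1126 CPM) than T-IP (149.8 to 436 and 29.4 to 63.3) or neonatal LMPP (142 to 769.7 and 40.7 to 477). Sex is therefore mixed with age where embryos or neonates were compared with adults, and also enters T-IP against neonatal ETP and neonatal ETP against neonatal LMPP. Among the calls, 4 of the 25 genes higher in neonatal than adult HSC were Y-linked. Whether the progesterone receptor gene Pgr, counted in adult ETP, follows sex or age was not tested.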

How the results depend on the processing

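The GC and length offset and the fit without 4 libraries that stood apart were chosen only after the result was seen, and the other alternatives were set in advance. Counts of genes past the threshold and their balance of directions depended on the processing. T-IP against fetal liver LMPP had 6 genes higher and 12 lower, but 112 and 64 by DESeq2, 142 and 33 with only the groups compared and 80 and 44 without the 4 libraries. Neonatal against adult ETP had 10 higher and 17 lower, but 638 and 508 by DESeq2, and 1268 and 503 without adult ETP replicate 2. Neonatal against adult HSC had 25 higher and 6 lower, but 7 and 7 with only the groups compared, 85 and 89 by limma and 25 and 16 with the GC and length offset. With only the groups compared, T-IP against adult ETP went from 1645 and 1377 to 700 and 772, and adult ETP against adult LMPP from 528 and 734 to 25 and 18. By limma, neonatal LMPP against HSC went from 211 and 208 to 252 and 570. Among 304 called genes that the text names or that rank highest by the naming rule, no direction reversed under any alternative run, and 187 stayed past the threshold under every one. Of 72 called lists, 34 did. Calls were lost for 76 of 302 genes with only the groups compared in the fit, where fewer libraries share the estimate of spread, and for 82 of 304 when 1 library was left out. The block lost 8 of 304, no filter 6 of 304, and RLE size factors 1 of 234. DESeq2 lost 3 of 234 and limma on the deposited RPKM 5 of 121, in comparisons without T-IP, for which it was not run. The GC and length offset lost 6 of 234 and the fit without 4 libraries 9. In the second table, pseudocounts of 0.1 and 5 lost 3 and 2 of 70 calls, quantile normalization 1 and median centring none.

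With an estimated correlation (camera), 29 of 72 called lists were no longer past the threshold, and the early lymphoid list of DN2 against E12.5 ETP changed the direction of its test (camera adjusted p=0.868), while its median was 0.14 under both. Camera tests a list against the other genes, while fry asks for direction alone, and members of that list went both ways. With only the groups compared, 13 of 71 called lists were lost, with 1 library left out 9 of 72, with the GC and length offset 5 of 56 and without the 4 libraries 2 of 56.

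The counts that moved by more than 1.5 times are given by setting, and the cause was not tested unless stated. Without a filter there were 33 for T-IP against fetal liver LMPP, 68 for neonatal ETP against neonatal LMPP, 15 for the difference of differences, 49 for neonatal ETP against adult ETP, 48 for neonatal HSC against adult HSC and 173 for E12.5 ETP against T-IP. The stricter filter gave 5 for the difference of differences and 44 for neonatal ETP against adult ETP. DESeq2 gave 176 for T-IP against fetal liver LMPP, 1441 for T-IP against AGM HSPC, 1111 for T-IP against neonatal ETP, 253 for neonatal ETP against neonatal LMPP, 2549 for adult ETP against adult LMPP, 65 for the difference of differences, 1146 for neonatal ETP against adult ETP, 916 for fetal liver LMPP against neonatal LMPP, 941 for neonatal LMPP against neonatal HSC and 187 for neonatal HSC against adult HSC, and on simulated data it made more true and more false calls than edgeR. By limma on the deposited RPKM there were 86 for neonatal ETP against neonatal LMPP, 155 for neonatal ETP against adult ETP, 518 for fetal liver LMPP against neonatal LMPP, 822 for neonatal LMPP against neonatal HSC and 174 for neonatal HSC against adult HSC.

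With the GC and length offset there were 36 for T-IP against fetal liver LMPP, 20 for the difference of differences, 97 for neonatal ETP against adult ETP, 631 for fetal liver LMPP against neonatal LMPP and 640 for neonatal LMPP against neonatal HSC. Without the 4 libraries there were 124 for T-IP against fetal liver LMPP, 1715 for T-IP against AGM HSPC, 134 for neonatal ETP against neonatal LMPP, 63 for the difference of differences, 540 for neonatal ETP against adult ETP, 1814 for fetal liver LMPP against neonatal LMPP, 1274 for neonatal LMPP against neonatal HSC and 52 for neonatal HSC against adult HSC. With only the groups compared edgeR gave 175 for T-IP against fetal liver LMPP, 1760 for T-IP against AGM HSPC, 1472 for T-IP against adult ETP, 0 for neonatal ETP against neonatal LMPP, 43 for adult ETP against adult LMPP, 4 for the difference of differences, 0 for neonatal ETP against adult ETP, 20 for neonatal LMPP against neonatal HSC and 14 for neonatal HSC against adult HSC. Both counts of 0 stand beside 1270 and 2939 genes with an unadjusted p under 0.05 in the fit of all groups, where DESeq2 called 253 and 1146 and limma 86 and 155. RLE size factors kept each of the 11 counts of the first table within 1.5 times, with 3 genes for the difference of differences, 2 higher and 1 lower.

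With 1 library left out, the lowest and highest counts were 3 to 36 for T-IP against fetal liver LMPP, 520 to 579 for T-IP against AGM HSPC, 310 to 427 for T-IP against neonatal ETP, 1353 to 3930 for T-IP against adult ETP, 5 to 43 for neonatal ETP against neonatal LMPP, 141 to 2510 for adult ETP against adult LMPP, 2 to 18 for the difference of differences, 6 to 1771 for neonatal ETP against adult ETP, 108 to 919 for fetal liver LMPP against neonatal LMPP, 109 to 621 for neonatal LMPP against neonatal HSC, 16 to 29 for neonatal HSC against adult HSC and 143 to 207 for E12.5 ETP against T-IP. DN2 against E12.5 ETP stayed within 1.5 times, at 1227 to 1427. Adult LMPP with 1 library left is assumed to vary like the other groups.

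The replicate block gave 1905 for adult ETP against adult LMPP and moved no other count beyond 1.5 times. Replicate numbers matched best across neonatal ETP and LMPP (r = 0.361, 0.0472 and 0.314). In both, r with GC content rose from replicate 1 to 3. T-IP 3 also matched neonatal ETP 3 (0.289), so shared handling is not shown. Simulated for T-IP against fetal liver LMPP, edgeR recovered 7.46% of 2-fold changes and DESeq2 19.4%, so most of that size were missed. Whether depth or spread between replicates set these shares was not tested.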

Other observations

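No test was added for these values, and genes named here outside the naming rule were chosen after their values were seen.

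Among the genes higher in DN2 than in E12.5 ETP, in RPKM and by limma, were Gzma (3944±104 against 85.8±65.9, adjusted p=1.11e-05) and Gzmb (564±91.6 against 3.16±2.43, adjusted p=2.13e-08), granzymes of killer cells, Gal (449±133 against 3.09±3.29, adjusted p=3.96e-07), a neuropeptide precursor, and Insl5 (79.5±15.6 against 0.523±0.590, adjusted p=3.60e-08), an insulin-like peptide. The enzyme genes Akr1c13 (1628±17.2 against 31.4±30.1, adjusted p=1.20e-06) and Fbp1 (156±24.1 against 1.16±1.57, adjusted p=3.91e-07) were higher too. The gate gene Flt3 (0.730±0.281 against 58.8±5.45) was lower. Tbc1d24 lay at 30.2±1.58 RPKM in E12.5 ETP and was listed at 0 in each of the 6 other libraries of the second run. Whether this comes from the cells or from how that table was made was not tested.

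Ifi44 and Lin28b follow in the 9 groups of the first run. The interferon response gene Ifi44 was at 0.448±0.201 CPM in T-IP, 0.409±0.427 in fetal liver LMPP and 5.17±5.47 in AGM HSPC. It was at 27.7±2.04, 13.6±9.08 and 174±173 in neonatal ETP, LMPP and HSC, and 118±30.6, 170.2±24.0 and 297±132 in the adult groups. The let-7 antagonist Lin28b ran the other way, at 101±30.6, 125±40.9 and 72.6±1.86 CPM in these E11.5 groups, 12.04±9.06, 25.6±15.7 and 21.8±5.74 in neonatal ETP, LMPP and HSC, and 0.0447±0.0774, 0.0870±0.123 and 0.895±0.883 in the adult groups in the same order.

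In T-IP, Hes1 was at 4.28±3.11 CPM in the first run and 1.44±0.412 RPKM in the second. Nrarp was at 0.185±0.321 CPM and 0.135±0.163 RPKM. Cd7 read 200.3±90.8 CPM and 73.8±6.87 RPKM, and Mpo 576±618 CPM and 425±156 RPKM. The units differ, so these levels were not compared by a test.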
